A study of Mus musculus with 3 samples.

How the data were processed

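Per the labels, B cells, NK cells and natural killer B cells were sorted from the spleens of wild-type C57/BL6 mice of 8 weeks, total RNA was extracted with TRIZOL, double-strand cDNA was made with oligo dT primers, and the Cy3-labelled product was hybridised to NimbleGen expression arrays, 1 array per population. The gate that separated the populations is not given in the sources used here. The labels' sorting text names long-term hematopoietic stem cells for all 3 samples, so the groups were taken from the sample titles and the cell type fields. The authors deposited 1 intensity per transcript and array, made with RMA per the submitters' processing notes, which give no version; per the file headers 44155 of the 44170 transcripts are measured by 3 probes, and coordinates are on build MM9. The deposited intensities are on a linear scale and their quartiles nearly coincide between arrays, so no further normalization was applied. A table of the series holds the same intensities, with a largest difference of 0. The authors also deposited tables of transcripts at least 2-fold different between NKB and B and between NKB and NK, whose log2 ratios were recomputed from the arrays. Those log2 ratios, as deposited by the authors, are plain ratios of 2 arrays, without a test.

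Gene symbols came from the array annotation in the deposited files. They were brought up to date by gene identifier with a mouse reference table (GRCm38.p6), used for names only, which held 39057 of the 44170 transcripts and changed the symbol of 5650. The 2284 transcripts without a symbol were left out of gene counts, except for T cell receptor and immunoglobulin transcripts, which were counted apart. Transcripts of 1 symbol were averaged on the log2 scale, giving 24171 genes, of which 10215 had 2 or more probe sets. The detection level of each array was the 95th percentile of 924 olfactory and vomeronasal receptor genes, which spleen cells are taken not to express. Values under it were set to it, so a difference against such a value is a lower bound. Genes were called at a 2-fold difference between 2 arrays. With 1 array per population no test was possible and no p-value is given. The groups, comparisons, detection level, threshold, gene lists and alternatives were fixed before the data were examined.

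The noise between arrays was gauged within the data. Without the detection level, 20.9% of the olfactory and vomeronasal genes differed at least 2-fold between NKB and B, 21.0% between NKB and NK and 14.0% between NK and B. Of the genes called on their first probe set, the next probe set had the same direction in 66.9%, 69.4% and 72.4%, and the standard deviation between probe sets of a gene was 1.27, 1.36 and 0.84 on the log2 scale. The steps were tested on simulated data with 200 changed genes and a noise (log2) of 0.467 on the B, 0.513 on the NK and 0.733 on the NKB array, solved from the spread of the olfactory and vomeronasal genes in the 3 comparisons. For NKB against B, 54.8% of genes changed 2-fold, 88.2% of those changed 4-fold and 94.9% of those changed 8-fold were called, and 4.23% of unchanged genes among 24171. For NKB against NK these were 53.3%, 93.7%, 92.2% and 4.6%, and for NK against B 49.4%, 87.1%, 96.6% and 2.66%. A simulated mixture of the observed B and NK values with an NK share of 0.3 and noise on NKB alone gave back 0.263 from 129 genes higher in B and 0.333 from 126 genes higher in NK. With noise on all 3 arrays and genes chosen on the noisy values, 200 simulated mixtures gave back 0.470 and 0.235 on average. All simulations gave every gene the noise of the olfactory and vomeronasal genes. The spread between probe sets of a gene was larger, so the simulated counts of unchanged genes called can be too low. The precision of every value is limited by the number of arrays. Bootstrap intervals resampled genes within these arrays, and genes are not independent, so the intervals do not measure the spread between arrays or animals.

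Lists of genes for lineage, function and other cell types, 35 in all, were written beforehand. A list's genes count as measured where at least 1 of the 2 arrays compared was above its level, and each median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Because a gene dim in B or NK counts as measured only if NKB is above its level, these ranks are not reported, and counts over all members on the array were ranked instead among random lists matched on the intensity of the array compared against. A further 11 lists, for kidney segments, other tissues, sex-linked genes and genes shared by leukocytes, were added after the leading genes had been seen. The genes named are the 10 with the largest and the 10 with the smallest difference in each comparison, the 10 leading genes above both and below both other arrays, the 2 largest and 2 smallest members of each list, and 17 genes fixed in advance, leaving out predicted and clone names. Other genes are named as members of a list and were chosen after their values were seen. The values of 2 list members are not reported here and are not drawn, although the list counts and medians include them. The position of NKB was (NKB - B)/(NK - B) on the log2 scale over genes at least 4-fold different between NK and B, and the NK share of a mixture was fitted by least absolute deviations on the linear scale.

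The alternatives were detection levels at the 99th percentile, at the array median or none, thresholds of 1.5-fold and 4-fold (2-fold and 8-fold for the position), the brightest probe set of a gene, each probe set by itself, a new quantile normalization, arrays shifted to equal medians, and the series table. Requiring every probe set of a gene to pass, and the rule of the deposited tables, were added after the data had been seen. The standard errors that the files give per transcript were not used here. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.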

Results

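Total RNA from 3 sorted populations of wild-type C57/BL6 mouse spleen at 8 weeks of age was profiled on single-colour expression arrays: B cells, natural killer (NK) cells and the population that the titles call natural killer B (NKB) cells. Each population was hybridised to 1 array, so there are no replicates, no test was possible, and the number of arrays limits the precision of every value below. Each array held 44170 transcripts, which carried 24171 gene symbols. The median intensity was 64.3 on the B array, 64.8 on the NK array and 65.1 on the NKB array, and the 5000 random control probes averaged 39.6, 38.7 and 43.1. Taking as the detection level the intensity that 95% of 924 olfactory and vomeronasal receptor genes stayed under, 149 for B, 137 for NK and 135 for NKB, 5650 genes were detected on the B array, 6075 on the NK array and 6033 on the NKB array. Of the 8825 genes detected on any array, 3388 were detected on all 3. The sort gate is not given in the sources used here, and the sorting text that accompanies all 3 samples names long-term hematopoietic stem cells, not the populations of the titles. Of 17 stem and progenitor genes on the array, 3 were detected on B, 4 on NK and 3 on NKB. Below, a gene is called higher or lower when its intensities differed at least 2-fold, and a fold is marked "at least" where the dimmer array was under its detection level.

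The comparison of NK with B cells gives the reference against which the NKB array was read. The genes that define each lineage were on opposite sides. The chemokine gene Ccl5 read 114 in B and 30429.7 in NK cells, and the granzyme gene Gzma read 40.7 and 9758. The interleukin receptor chain gene Il2rb, whose product NK cells need to survive, was at least 34.4-fold higher in NK, and Prf1, which encodes the pore-forming perforin, was at least 22.0-fold higher. On the B side, the B cell receptor signalling chains Cd79a and Cd79b were at least 36.3-fold lower and 54.0-fold lower in NK. In all, 537 genes were higher and 717 lower in NK than in B. On simulated arrays with the noise of the olfactory genes 638 of 23971 unchanged genes were called in either direction. With the arrays shifted to equal medians over shared genes the split was 726 higher and 465 lower, because the shift raised all NK values against B. The median log2 difference over genes detected on any array went from -0.12 to 0.072. The value of -0.12 is the offset between the detection levels of NK (7.0993) and B (7.2183), which genes under both levels take. It is not a difference in expression.

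Of the NK cell identity genes, 23 of 26 measured were higher in NK than in B (median log2 difference 2.43) and none was lower. The largest differences after Ccl5, Gzma and Il2rb were those of the granule membrane gene Nkg7 (log2 difference 4.59), Prf1 (4.46), the cathepsin gene Ctsw (4.42) and the signalling adaptor Tyrobp (4.26). The chemokine Ccl3 (6.06), the lysosomal protease gene Ctsd (4.14) and the membrane protein gene Fxyd5 (4.28) were also among the 10 largest. Among Ly49 receptors, which recognise MHC class I, 17 of 21 on the array were higher, led by Klra13-ps at 5176 and Klra3 at 2489; these genes are close paralogs, so the signal of single members is uncertain. The cytotoxic list had 9 of 15 higher and the NK receptor adaptor list 8 of 10, including Fcer1g at 33.0 and 1793. Ifng, the effector cytokine of NK cells, read 38.6 in B and 1554 in NK, and the transcription factor Eomes read 36.5 and 583. The receptor gene Klrb1c was at least 6.19-fold higher in NK, whereas Ncr1 read 159 and 308, with 1 probe set at 81.8 and 99.7 and the other at 307.6 and 950.3.

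B cell identity genes were lower in NK for 23 of 25 measured (median -3.21), the exceptions being Vpreb3 and Tnfrsf13b, whose NK values were under the detection level. The master regulator of the B lineage, Pax5, read 1310.3 in B and 77.4 in NK, and its partner Ebf1 read 581 and 44.7. Of the antigen presentation genes 12 of 13 were lower in NK (median -3.57). The largest of these was H2-DMb1, which helps load peptides and read 13169.6 in B and 205 in NK, followed by its close paralog H2-DMb2 at 6514 and 71.3. Ighm, the heavy chain of IgM, was 13.3-fold lower in NK, the variable segment Ighv14-2 was at least 24.6-fold lower, and 4 of 5 immunoglobulin genes were lower. Icosl, a costimulatory ligand, was at least 18.8-fold lower, Pou2af1, a B cell coactivator, at least 16.8-fold lower, and the actin-binding gene Cnn3 25.7-fold lower. B cell receptor signalling had 12 of 20 lower and none higher, and the Toll-like receptor list 5 of 8 lower. Sval2, a gene of the seminal vesicle antigen family, read 4177 in B and 34.7 in NK.

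Genes of other cell types also differed between the NK and B arrays. Monocyte and macrophage genes were higher in NK for 12 of 25 on the array, led by Lyz2 at 93.7 in B and 2388 in NK and the complement gene C1qc at 92.2 and 1247. Erythroid genes were higher for 4 of 20, with Hbb-b1 at 252 and 2083. T cell genes were higher for 3 of 19, with Cd3e, a chain of the T cell receptor complex, at 200 and 534 and Thy1 at 222 and 2260.3. Of 154 T cell receptor transcripts without a gene symbol, 65 were detected in NK, 19 in B and 28 in NKB. The B1 cell list was higher in NK for 6 of 12 on the array, with Itgb1 at 213 in B and 1609 in NK. Ribosomal protein genes were lower in NK for 9 of 38 (median -0.60), while none of 27 oxidative phosphorylation genes and none of 16 glycolysis genes was higher or lower. Of the genes with several probe sets, 56 of 152 higher and 106 of 241 lower ones passed on every one, and with the detection level at the 99th percentile the counts were 174 and 269.

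NKB cells were next compared with B cells, to ask which B cell transcripts they carry and which they add. Of 25 B cell identity genes 23 were detected on the NKB array, and a few NK genes were far above their B level. Pax5 was 8.36-fold higher in NKB at 10954, on a single probe set, Ms4a1, which encodes the surface protein CD20, was 2.02-fold higher at 2562, and Cd79a read 4056 against 4977 in B. Ccl5 was at least 59.9-fold higher in NKB at 8916, Gzma at least 27.5-fold higher at 4098 and Fcer1g at least 8.53-fold higher at 1270.5. In all, 1102 genes were higher and 1148 lower in NKB than in B. The simulated noise of the olfactory and vomeronasal genes gave 1013 calls among 23971 unchanged genes. The split depends on scaling, with 971 higher and 1244 lower after a new quantile normalization and 1223 and 1015 with the arrays shifted to equal medians.

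Of the B cell identity genes, 2 were higher, 9 lower and 14 neither in NKB than in B (median -0.30). Random lists of the same size, matched on intensity in B, averaged 9.08 lower genes. The members near their B level included Ebf1 at 581 in B and 545 in NKB, Bank1 at 1499 and 1465 and Cd72 at 545 and 535. The Src-family kinase gene Blk (2.90-fold lower), the inhibitory receptor Cd22 (2.09-fold lower), the transcription factor Pou2f2 (3.79-fold lower) and the IgM receptor gene Fcmr (2.77-fold lower) were among the lower ones. Ighm read 10982 in B and 6754 in NKB, and 3 of 6 immunoglobulin genes were lower, while Jchain, which joins IgM subunits, was at least 3.36-fold higher. B cell receptor signalling had 2 higher and 6 lower of 21, with the adaptor Malt1 2.14-fold higher, although 1 of its probe sets read lower, and the kinase gene Syk 3.92-fold lower. Antigen presentation genes were lower for 6 of 14: H2-Ab1, an MHC class II chain, was 7.86-fold lower in NKB at 1239.5, the transactivator Ciita read 954 and 205, and H2-Ob was at least 12.0-fold lower with unequal folds on its probe sets, whereas H2-DMb1 read 13169.6 and 9954. The follicular and transitional list had 1 higher and 4 lower of 10, the marginal zone list 2 higher and 2 lower of 8 and the plasma cell list 4 higher and 0 lower of 9, the last led by Irf4, a regulator of B cell activation, which was 5.27-fold higher.

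Of the 26 NK cell identity genes on the array, 1 was detected in B and 14 in NKB, and 6 were higher in NKB than in B. The 6 were Ccl5, Gzma, Fcer1g, the migration receptor S1pr5 (at least 3.43-fold higher), Ctsw (at least 2.28-fold higher) and Klri2 (at least 2.09-fold higher). Several defining NK genes were dim on the NKB array, so that a fold against the detection level of B stayed under 2: Il2rb read 151, Klrb1c 191, Eomes 132 and Nkg7 64.5, and Prf1 and Gzmb read 288 and 233. Every probe set of Klrb1c and Eomes nevertheless read higher in NKB than in B. The authors' tables, which use no such level, list Klrb1c (3.13-fold to 8.10-fold over 3 transcripts), Eomes (3.12-fold to 4.19-fold over 3), Prf1 (5.58-fold) and Gzmb (3.65-fold) as higher in NKB. Ly49 receptors were higher for 6 of 21 on the array, led by Klra13-ps at 1066 and Klra8 at 623. The cytotoxic list had 3 higher and 1 lower of 11, the NK adaptor list 1 higher and 0 lower of 5, and the chemokine list 2 higher and 0 lower of 5, which were Ccl5 and Ccl3, at 139 in B and 2399.9 in NKB. The B1 cell list had 3 higher and 0 lower of 5 and the adhesion list 4 higher and 2 lower of 17, with the integrin chain Itgb1 4.40-fold higher and Itgb7 at least 9.20-fold lower.

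Apart from Ccl5 and Gzma, the genes with the largest excess over B were the calcium-binding nucleobindin gene Nucb2 (at least 34.8-fold higher), the urea-cycle enzyme gene Ass1 (23.2-fold higher), the small nucleolar RNA Snord82 (at least 22.4-fold higher), Hbb-b1 (22.2-fold higher), the iron carrier transferrin gene Trf (at least 20.1-fold higher), the chromatin protein gene Hmgb2 (19.4-fold higher), the respiratory chain gene Ndufa12 (at least 17.0-fold higher) and the NF-kappaB subunit gene Rel (16.2-fold higher). The largest deficits were those of Sval2 (at least 30.9-fold lower), the neuronal factor Neurod6 (at least 17.9-fold lower), the muscle kinase gene Srpk3 (at least 15.7-fold lower), H2-Ob, the cytokine Tnfsf11 (at least 11.5-fold lower), the acyl-CoA synthetase gene Acsf2 (11.04-fold lower), the receptor kinase gene Ret (10.8-fold lower), Serpinb3a (at least 10.3-fold lower), Mesp1 (at least 9.59-fold lower) and the odorant receptor gene Olfr447 (9.46-fold lower). Except for Ass1 and H2-Ob, these genes had a single probe set each.

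Monocyte and macrophage genes were higher in NKB than in B for 11 of 25 on the array, of which 3 were detected in B and 16 in NKB, including C1qc at 1972, C1qb at 1951, the lipid carrier Apoe at 592 in B and 4986 in NKB, and Lyz2 at 671. Erythroid genes were higher for 4 of 20 on the array, with Hbb-b1 at 5583 and Hba-a1 at 597 in B and 3468 in NKB. T cell genes had 1 higher and 0 lower of 5, the higher gene being Thy1, while Cd3e read 200 in B and 146 in NKB. Of the 1102 higher genes 422 were under the detection level in B, and of the 1148 lower genes 458 were under it in NKB. Of the higher genes with several probe sets, 121 of 400 passed on every one, and of the lower genes 103 of 375, and with the detection level at the 99th percentile the counts were 460 higher and 702 lower.

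**Figure D1:**
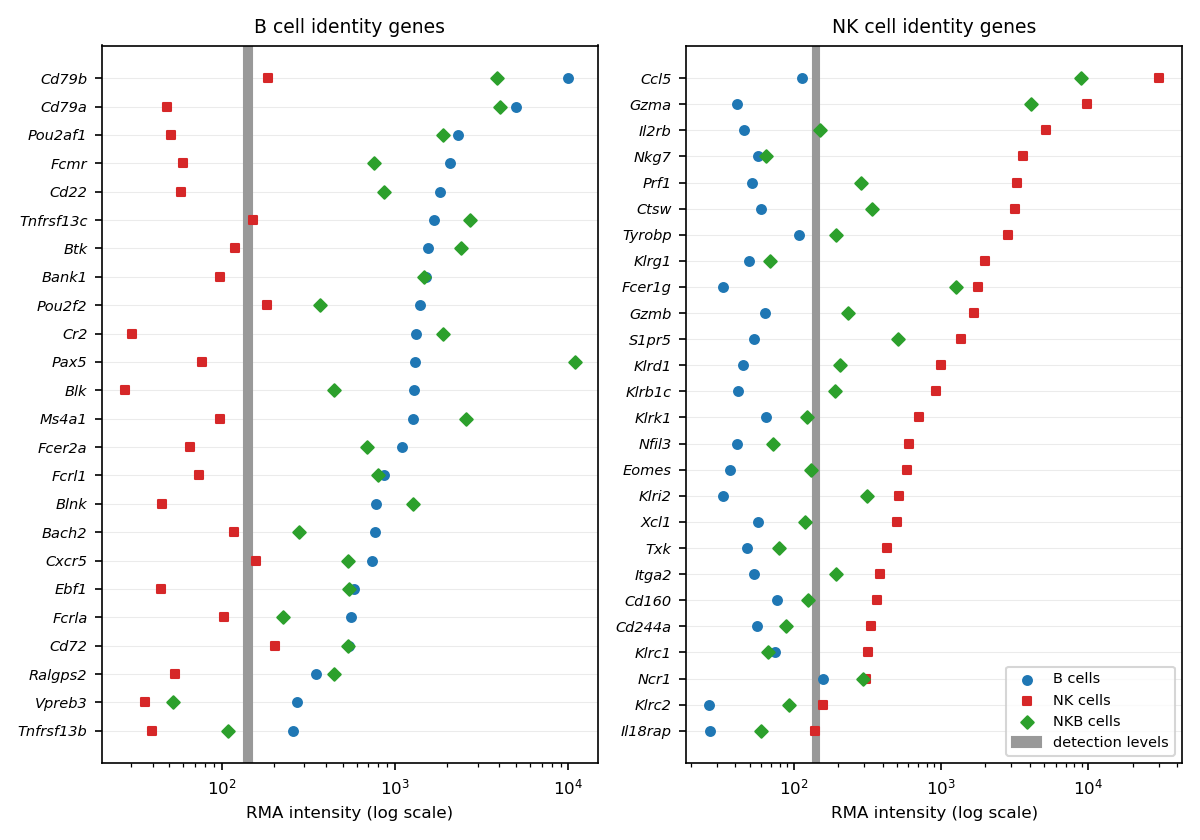
RMA intensity (log scale) of B cell identity genes (left) and NK cell identity genes (right) on the array of each population, with 1 point per array; the grey band spans the 3 detection levels. NKB points lie near the B points for most B cell genes, with Pax5 at 10954 against 1310 in B, and between the B and NK points for Ccl5 (8916) and Gzma (4098), while Nkg7 (64.5) and Klrg1 (68.6) stay under the band.

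The comparison of NKB with NK cells asks which NK transcripts the NKB cells share and which they lack. Several B cell genes were among the 10 with the largest excess over NK, and most NK identity genes were lower in NKB. Pax5 was at least 79.9-fold higher in NKB than in NK, H2-DMb1 48.5-fold higher, Cd79a at least 29.6-fold higher and Cd79b 21.1-fold higher. Il2rb was 33.9-fold lower in NKB at 151 against 5119, and Nkg7 was at least 26.5-fold lower at 64.5 against 3584. Ccl5 was 3.41-fold lower and Gzma 2.38-fold lower, whereas Fcer1g read 1793 in NK and 1270.5 in NKB. In all, 1442 genes were higher and 1233 lower in NKB than in NK. The simulated noise of the olfactory and vomeronasal genes gave 1103 calls. A new quantile normalization turned the split to 1229 higher and 1454 lower, and the shift to equal medians to 1293 and 1411.

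B cell identity genes were higher in NKB than in NK for 22 of 23 measured (median 2.55), with Btk, the kinase of B cell receptor signalling, at 119.7 in NK and 2409 in NKB, and Tnfrsf13c, the BAFF receptor gene, at 151 and 2712. Cd24a, a member of the follicular and transitional list, read 132 and 3690.3. Ms4a1 was at least 18.7-fold higher and Ebf1 at least 3.97-fold higher. B cell receptor signalling had 13 higher and 1 lower of 21, antigen presentation 8 higher and 0 lower of 12, immunoglobulin genes 3 higher and 0 lower of 6, the follicular and transitional list 5 higher and 0 lower of 9, the marginal zone list 3 higher and 2 lower of 7 and the plasma cell list 4 higher and 0 lower of 9. Cd74, the invariant chain of MHC class II, read 679 in NK and 6344 in NKB, and Ighm was 8.17-fold higher. Toll-like receptor genes had 3 higher and 0 lower of 8, with Cd180, a B cell surface receptor, at least 4.97-fold higher. Interferon-stimulated genes had 8 higher and 2 lower of 16, led by Ifit3 at 145 and 1130.2. Besides the B cell genes, Rel (59.8-fold higher), Nucb2 (at least 37.8-fold higher), Ass1 (at least 30.0-fold higher), Snord82 (at least 24.4-fold higher) and the RNA-binding protein gene Hnrnpul2 (20.8-fold higher) were among the 10 largest.

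NK cell identity genes were lower in NKB than in NK for 21 of 26 measured (median -1.83), and the other 5, which included Fcer1g and Klri2, differed less than 2-fold. Ncr1 was among the 5 only as an average. In NKB, 1 of its probe sets read 315.4 against 950.3 in NK, and the other, under the detection level in NK, 273.8 against 99.7. Klrb1c, which encodes the NK1.1 antigen, was 4.83-fold lower at 191 against 922, Eomes at least 4.31-fold lower, Gzmb 7.24-fold lower and Prf1 11.4-fold lower. Ifng was at least 11.5-fold lower and read 67.8 in NKB. Ly49 receptors were lower for 16 of 19 (median -2.14), with Klra4 at 1552 in NK and 88.4 in NKB. The cytotoxic list had 1 higher and 10 lower of 15, the adaptor list 0 higher and 7 lower of 10, the chemokine list 0 higher and 4 lower of 7, with a median of -1.77 that was 0.11 with the detection level at the array median, and the adhesion list 2 higher and 9 lower of 20. Tyrobp (14.7-fold lower), the inhibitory receptor gene Klrg1 (at least 14.6-fold lower), the chemokine Ccl4 (at least 14.3-fold lower), the selectin ligand Selplg (13.8-fold lower), the semaphorin gene Sema4a (at least 19.2-fold lower) and the peptidoglycan recognition gene Pglyrp1 (at least 20.8-fold lower) were among the 10 lowest. Among transcription factors the list had 7 higher and 8 lower of 25; Irf4 was 11.8-fold higher and Id2, which NK cells need to develop, 4.33-fold lower, and Runx3 read 956 and 47.5.

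Monocyte and macrophage genes went both ways between NKB and NK, with 6 higher and 7 lower of 20 measured. Apoe (674 in NK and 4986 in NKB) and Vcam1 (175 and 646) were higher, and Lyz2 (2388 and 671) and Cd68 (769.7 and 187) lower. Erythroid genes had 1 higher and 0 lower of 7 and T cell genes 0 higher and 3 lower of 6, with Cd3e 3.65-fold lower and Tcf7, a T and NK cell factor, at least 8.16-fold lower. Of the 1442 higher genes 614 were under the detection level in NK, and of the 1233 lower genes 596 were under it in NKB. On genes with several probe sets, 171 of 580 higher and 109 of 387 lower genes passed on every one, and with the detection level at the 99th percentile the counts were 576 and 705.

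**Figure D2:**
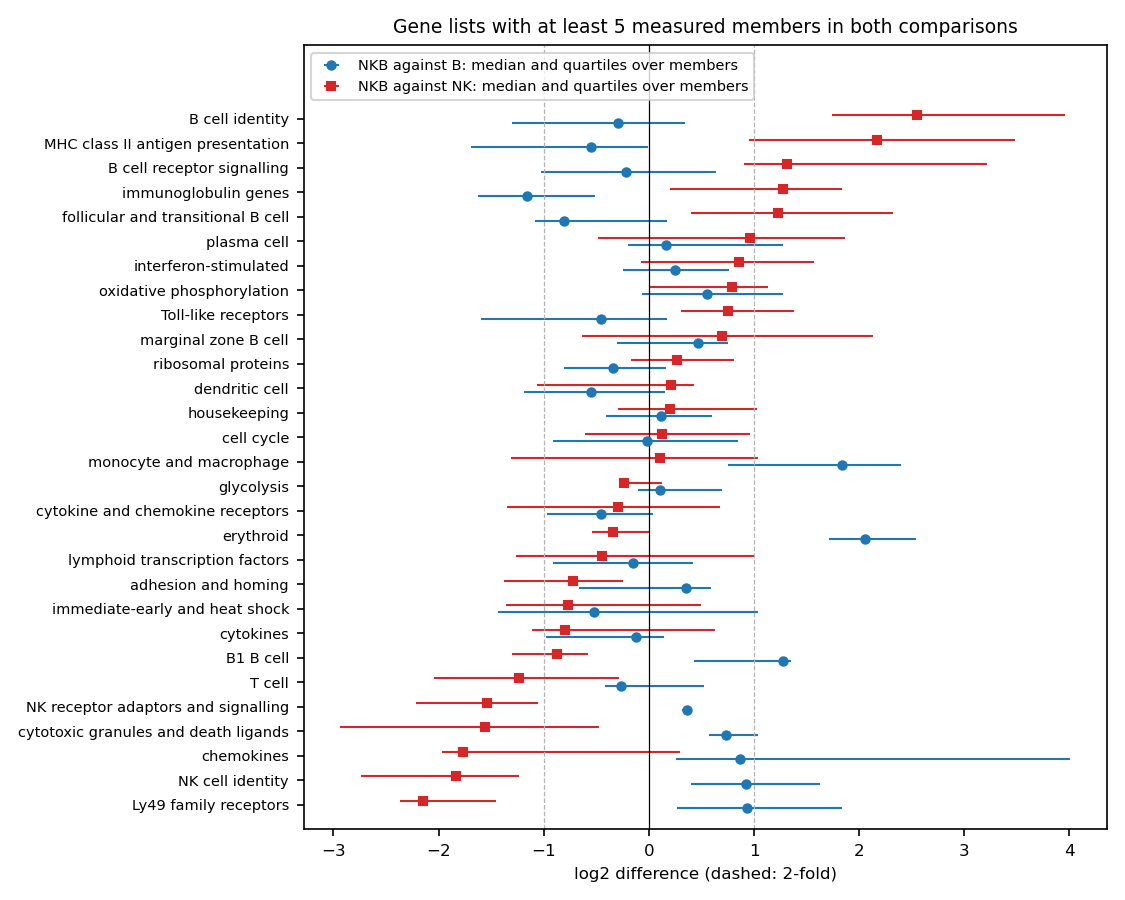
Median log2 difference (point) and quartiles (line) over the measured members of each fixed gene list, for NKB minus B (blue circles) and NKB minus NK (red squares), for 29 lists with at least 5 measured members in both comparisons. B cell identity lies at -0.30 against B and 2.55 against NK, and NK cell identity at -1.83 against NK; positive medians of lists detected mainly on the NKB array, such as NK cell identity against B, follow from which members count as measured.

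The NKB array was then set against both others at the same time, to see whether its genes lay between those of B and NK cells. Among the 129 genes at least 4-fold higher in B than in NK, the median position of NKB was 0.40 (quartiles 0.067 and 0.79), where 0 is the B array and 1 the NK array. Among the 126 genes at least 4-fold higher in NK, it was 0.10 (quartiles -0.061 and 0.47). These medians depend on the threshold: they were 0.55 and -0.071 over genes that differ at least 2-fold, and 0.26 and 0.27 over genes that differ at least 8-fold. The bootstrap interval of the second, over resampled genes, included 0 (-0.0325 to 0.176). It does not measure the spread between arrays. The median over genes higher in NK was -0.016 with the detection level at the 99th percentile, -0.0017 over single probe sets and 0.020 over the brightest probe sets. A gene under the main level in both B and NKB takes a negative position there by construction, because the NKB level (135) is lower than the B level (149). Such positions do not place NKB below B. The 126 genes higher in NK were not NK cell genes alone. They included the macrophage list members C1qb (position 1.39), C1qc (1.22), C1qa (1.08), Hmox1 (0.73), Lyz2 (0.54), Cd68 (0.12) and Lyz1 (-0.058). They also included the erythroid list members Hbb-b1 (1.47), Hba-a1 (1.04), Car2 (0.81) and Hba-a2 (0.75). All of these but Lyz1 lay above the median of 0.10. Of the 537 genes higher in NK than in B, 309 (57.5%) were detected in NKB and 91 were at least 2-fold above B there, while 416 were at least 2-fold below NK. Of the 717 genes higher in B, 573 (79.9%) were detected in NKB and 301 were at least 2-fold above NK, while 336 were at least 2-fold below B. Among the 537, 278 were under the detection level in B, and among the 717, 242 were under it in NK. The others were detected in both, so detection in NKB does not by itself mark 1 lineage. Both sets were chosen on these B and NK values. Noise in those values alone tends to place NKB below the array where a gene was higher and above the other. Across the 8825 detected genes, which are not independent replicates, Pearson's r was 0.732 between B and NK, 0.621 between B and NKB and 0.497 between NK and NKB, and Spearman's rho 0.637, 0.482 and 0.316. The noise estimated from olfactory and vomeronasal genes was 0.733 on the NKB array, 0.467 on B and 0.513 on NK. A noisier array by itself has lower correlations, so these values do not show that NKB is the most distinct population.

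In NKB, 925 genes lay at least 2-fold above both B and NK, and 573 at least 2-fold below both. The simulated noise of the olfactory and vomeronasal genes gave 375 and 144. Probe sets of a gene differed more than that noise, with a standard deviation of 1.27 against B and 1.36 against NK. The simulated counts can therefore be too low, and the surplus over them is not a count of real differences. On the measured arrays the same count was 336 above and 91 below for B against the other arrays, and 416 and 301 for NK. The larger noise of the NKB array by itself raises its counts against those of B and NK. The leading genes were Nucb2 (at least 34.8-fold above the brighter of B and NK), Ass1 (23.2-fold), Snord82 (at least 22.4-fold), Rel (16.2-fold, at 8866), Hnrnpul2 (16.0-fold, at 8664), the endosomal tetraspanin gene Cd63 (at least 15.4-fold), the fatty acid transporter gene Slc27a2 (at least 15.04-fold), the helicase gene Dhx9 (13.1-fold, with unequal folds on its probe sets), the histone gene H4c11 (at least 12.2-fold) and the mitochondrial carrier gene Slc25a10 (12.1-fold). Pax5 (8.36-fold) and Irf4 (5.27-fold) were also above both, as was Mki67, a marker of dividing cells, at 129 in B, 148 in NK and 994 in NKB. Of the oxidative phosphorylation genes 10 of 27 were higher than in B and 10 of 28 than in NK, led by Cox6c at 239, 176 and 2748. The lowest against both were Olfr447 (9.46-fold), Ret (8.72-fold), Itgb7 (at least 7.84-fold), the membrane protein gene Tmem88 (6.88-fold), Tnfsf11 (at least 6.87-fold), the epidermal gene Lce1h (at least 6.85-fold), the ATP synthase gene Atp5g3 (at least 6.45-fold), the defensin gene Defb9 (at least 6.41-fold), the kinase scaffold gene Cab39 (at least 5.81-fold) and the MHC class I gene H2-Q7 (5.72-fold, with unequal folds on its probe sets). Of the genes above both with several probe sets, 90 of 345 passed on every one, and of those below both 34 of 163; with the detection level at the 99th percentile 407 genes were above both and 346 below.

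**Figure D3:**
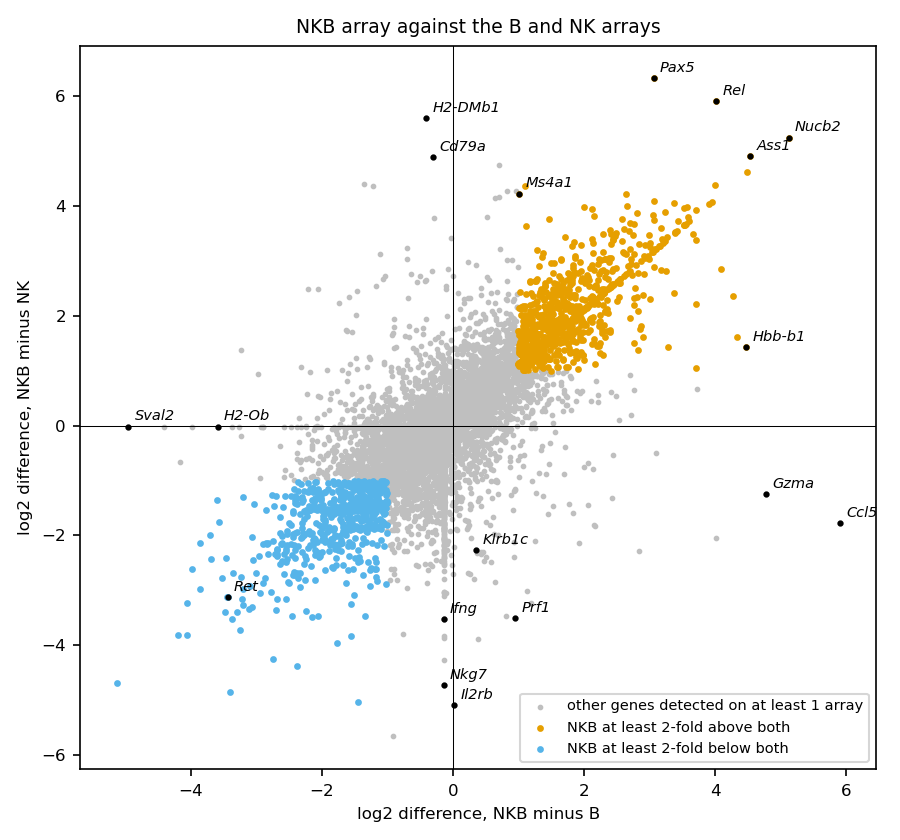
Log2 difference of NKB minus B (horizontal) and NKB minus NK (vertical) for the 8825 genes detected on at least 1 array, with 1 point per gene; orange points are the 925 genes above both and blue points the 573 below both. Pax5, Rel, Nucb2 and Ass1 lie at the upper right, Cd79a and H2-DMb1 at the top near the B value, and Ccl5 and Gzma at the lower right.

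Several of the genes above both are known from the proximal tubule of the kidney, which led to kidney gene lists written after the leading genes were seen. Ass1, Slc27a2, Slc25a10, the phosphate transporter Slc34a1, the inositol oxygenase gene Miox, Acsm1, Acaa1b and Rida were the 8 genes that prompted them, so their position above both is by construction; Miox read 30.9 in B, 49.5 in NK and 1407 in NKB. Of 55 further proximal tubule genes on the array, 4 were detected in B, 7 in NK and 26 in NKB, and 15 of the 55 were at least 2-fold above both. They included the amino acid transport gene Cltrn (34.5, 34.4 and 1093), Sord (41.8, 77.3 and 966), the anion transporter gene Slc22a8 (877 in NKB), Fbp1 (853) and Gpx3 (716). Members that were not 2-fold above both included Kap at 198, and Lrp2 at 75.1, Cyp2e1 at 53.0 and Slc13a1 at 112, the last 3 under the detection level. Of the genes of other kidney segments 3 of 26 on the array were above both, namely Aqp2 at 538, Umod at 369 and Aqp1 at 348. None of the genes on the array of liver (25), exocrine pancreas (16), small intestine (13), skeletal muscle (16) or brain (15) was at least 2-fold above both. In total 26 of the 925 genes above both were on the kidney lists.

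**Figure D4:**
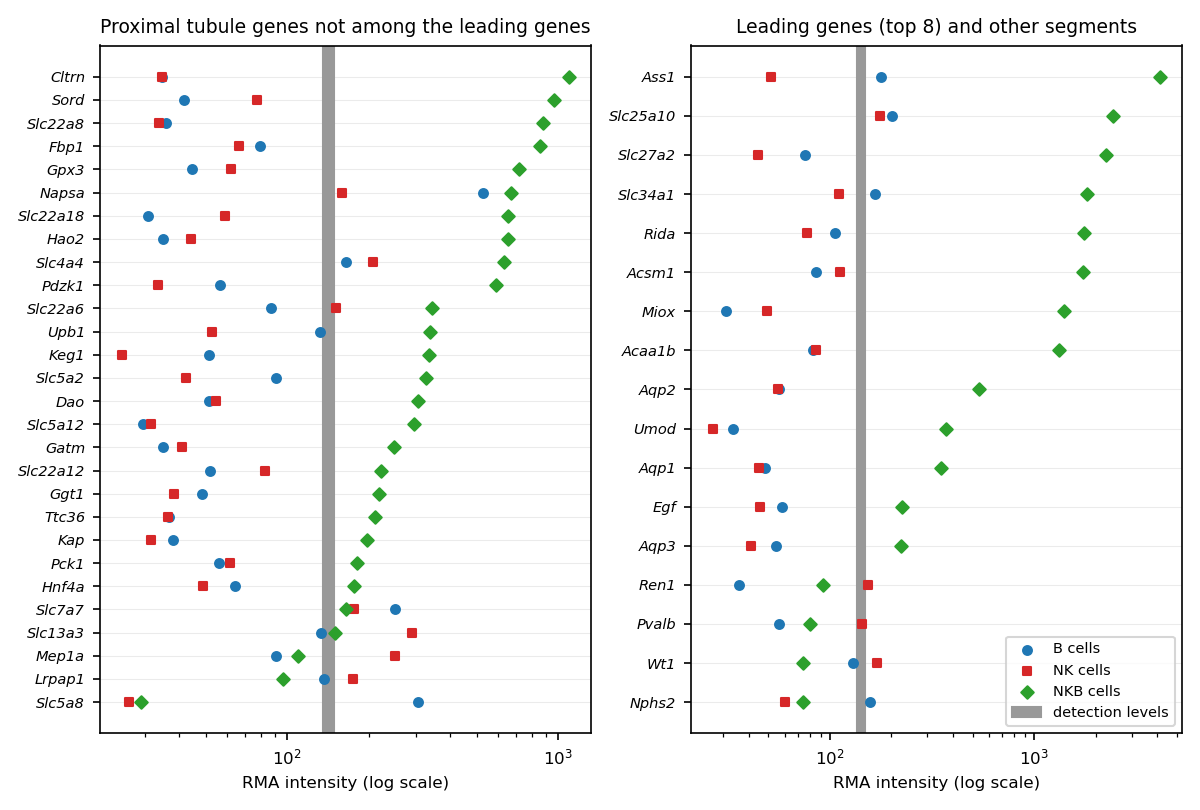
RMA intensity (log scale) of kidney genes on the B, NK and NKB arrays, with 1 point per array: proximal tubule genes that were not among the leading genes (left), and the 8 leading genes with genes of other segments (right); the grey band spans the detection levels. The NKB points reach 1093 for Cltrn and 4117 for Ass1, with the B and NK points of Cltrn at 34.5 and 34.4.

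Counts over all members on the array were ranked among 10000 random lists matched on the intensity of the array compared against, which describes these arrays only and was chosen after the counts were seen. For genes higher in NKB, B cell identity lay at percentile 100 against NK (22 of 25) and 25.8 against B (2 of 25). For genes lower in NKB than in B, B cell identity lay at 49.7 (9 of 25, where random lists averaged 9.08). B cell receptor signalling lay at 35.5 for such genes (6 of 21, random average 6.84) and antigen presentation at 83.7 (6 of 15, random average 4.30). NK cell identity lay at 100 for genes higher than in B (6 of 26) and at 100 for genes lower than in NK (21 of 26). For higher genes, the monocyte and macrophage list lay at 100 against B and 95.8 against NK, the erythroid list at 99.9 and 42.8, and the oxidative phosphorylation list at 99.96 and 99.7. Matched on the brighter of B and NK, the further proximal tubule genes above both lay at 100 (15 of 55, where random lists averaged 1.23), the other kidney segments at 98.75 and liver at 39.2.

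The cytokines named in advance were mostly dim. Il18 read 102 in B, 86.6 in NK and 232 in NKB, and with B and NK set to their detection levels it was at least 1.55-fold and 1.69-fold higher in NKB, under the 2-fold threshold. The tables the authors deposited list 1 of its 2 transcripts as higher, 3.03-fold against B and 6.38-fold against NK. Il12a read 72.5, 50.2 and 45.9 and Il12b 42.3, 32.8 and 43.4, all under the detection level. Tbx21 and Ighd had no probe set under those symbols. In the tables the authors deposited, 3075 transcripts were listed as higher and 4142 as lower in NKB than in B, and 3783 as higher and 4094 as lower than in NK, with folds of up to 101, 89.8, 141 and 170. Every listed transcript had an intensity of 100 or more on at least 2 of the 3 arrays, and 2759, 1313, 2802 and 1843 further transcripts with a 2-fold difference had such an intensity on only 1 array and were not listed. Of the 925 genes above both, 771 were listed as higher in both tables and 143 in neither, and of the 15 further proximal tubule genes above both 5 were listed in both and 10 in neither.

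On build MM9, which the files name, the array's transcripts of the genes discussed most were at the following positions. Pax5 (gene identifier 18507) was on chromosome 4, 44544379 to 45044662 and Ms4a1 (12482) on chromosome 19, 11325365 to 11340641. Cd79a (12518) was on chromosome 7, 25682532 to 25686877, Ighm (16019) on chromosome 12, 114656768 to 116831787, and Rel (19696) on chromosome 11, 23642136 to 23670912. Ccl5 (20304) was on chromosome 11, 83339280 to 83344003, Gzma (14938) on chromosome 13, 113884034 to 113891189, and Il2rb (16185) on chromosome 15, 78310978 to 78325469. Klrb1c (17059) was on chromosome 6, 128728502 to 128738613, Ass1 (11898) on chromosome 2, 31325789 to 31376190, and Nucb2 (53322) on chromosome 7, 123647928 to 123684098.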

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

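The counts that require every probe set of a gene, and those by the rule of the deposited tables, were chosen only after the results were seen, the second read off those tables. No paired analysis was possible because each population had 1 array. Of the alternatives' values, 26 counts of called genes stayed within 1.5 times the main count and 68 did not. Among list medians, 723 stayed within the main value's bootstrap interval, 28 moved out of it and 2 reversed. Among positions and mixture shares, 15 stayed within the main value's bootstrap interval and 7 did not. Of the values of single genes, 2593 stayed within 1.5 times, 831 moved and 14 reversed. Reversed means a change of sign where the main value was at least 2-fold. A change of sign of a smaller value counts as stayed or moved. The totals that stayed include the series table, whose values could not move. It supplied 8 of the 26 counts, 96 of the 723 list medians, 2 of the 15 positions and shares, and 440 of the 2593 single-gene values. The series table holds the same intensities, so it moved nothing, and a new quantile normalization kept all 8 counts within 1.5 times, although the split between higher and lower turned to 1229 and 1454 for NKB against NK and to 659 and 603 for NK against B. With arrays shifted to equal medians it turned in all 3 comparisons, to 1223 and 1015 for NKB against B, 1293 and 1411 for NKB against NK, and 726 and 465 for NK against B.

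Counts are listed in the order higher and lower in NKB than in B, higher and lower in NKB than in NK, higher and lower in NK than in B, and above and below both in NKB; the main ones are 1102, 1148, 1442, 1233, 537, 717, 925 and 573. With the detection level at the 99th percentile they were 460, 702, 576, 705, 174, 269, 407 and 346. At the array median they were 2076, 2087, 2462, 2402, 1211, 1251, 1581 and 1138, and without a level 3187, 3131, 3670, 3599, 2006, 1943, 2113 and 1716. By construction a lower level admits more dim genes, and 20.9% of the olfactory and vomeronasal genes pass 2-fold between NKB and B without one. A 1.5-fold threshold gave 1821, 2038, 2266, 2078, 1090, 1649, 1569 and 1128, and a 4-fold threshold 265, 248, 446, 285, 126, 129, 203 and 105, again by construction. Counting each probe set by itself gave 2655, 2441, 3247, 2616, 1185, 1518, 2260 and 1255, since a gene then counts more than once. Genes with several probe sets that all passed numbered 121, 103, 171, 109, 56, 106, 90 and 34, out of fewer genes tested. The rule of the deposited tables counts transcripts and gave 3075, 4142, 3783, 4094, 1720 and 2524 for the first 6. With the brightest probe set, 1865 genes were higher in NKB than in B, 2218 higher in NKB than in NK, 854 higher in NK than in B, 1585 above both and 867 below both; the cause was not tested. With arrays shifted to equal medians, 465 genes were lower in NK than in B, and the shift of all NK values against B is the cause by construction.

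The median for B cell identity kept its direction under all alternatives for NKB against NK and for NK against B. At the 99th percentile it was 1.06 for NKB against NK and -1.71 for NK against B, and for NK against B it was -3.69 at the array median and -3.70 without a level. The median for NK cell identity was 0.00028 for NKB against B at the 99th percentile, and 3.65 and 4.23 for NK against B at the array median and without a level. These follow from where dim values are set. The chemokine median for NKB against NK, -1.77, reversed to 0.11 at the array median and 0.44 without a level, because dim members then enter the list. The position of NKB over genes higher in B was 0.55 at a 2-fold and 0.26 at an 8-fold threshold, and over genes higher in NK -0.071 and 0.27, and 0.21 without a level. A gene higher in NK and under the main level in both B and NKB takes a negative position by construction, because the NKB level (135) is lower than the B level (149). Other causes of these shifts were not tested. The main value over genes higher in NK, 0.10, has an interval that includes 0 (-0.0325 to 0.176), within which the sign turned at the 99th percentile (-0.016) and over single probe sets (-0.0017), and the brightest probe sets gave 0.020. The mixture share of NK, 0.348 over both gene sets, was 0.669 from genes higher in B and 0.155 from genes higher in NK.

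Single genes reversed mainly at the 99th percentile, where the B or NK array is set to a level that lies above the NKB intensity: Pou2f2 (-0.12), Lta (-0.0397), Clec1b (-0.17) and Ms4a2 (-0.11) for NKB minus NK, and Ctsw (-0.29), Irak4 (-0.32), Clec1b (-0.22), Ms4a2 (-0.17) and Mx2 (-0.12) for NKB minus B, on the log2 scale. On single probe sets Pou2f2 read -0.24 for NKB minus NK, Malt1 -0.60, Cd55 -0.56 and Tm6sf1 0.48 for NKB minus B, and Pecam1 0.15 for NK minus B; the cause was not tested. Summed over the settings, 190 values of named genes were left out because no array compared was above the level in that setting. The same gene can have a value in other settings. Signal over background limits what can be said of dim genes: only 23.4% of genes on the B array, 25.1% on the NK array and 24.96% on the NKB array were above the level, and differences between 2 arrays that were both under it were not detectable.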

Other observations

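The tests of noise over all genes, of kidney RNA, and of the mixture on second probe sets, on fixed lists and by simulation, were chosen only after the results they measure were seen. Genes of cell division did not move together. Of the cell cycle list, 2 higher and 3 lower of 12 measured were called against B and 2 higher and 1 lower of 13 against NK. The proliferation gene Mki67 and the topoisomerase gene Top2a were the higher pair in both, Top2a with intensities of 53.8 in B and 432 in NKB, while the replication helicase genes Mcm4 (318, 394 and 129 in B, NK and NKB) and Mcm6 (428, 157 and 124) were lower than in B. Immediate-early and heat shock genes were called 6 higher and 7 lower of 23 against B, and 3 higher and 9 lower of 26 against NK. The early activation gene Cd69 read 117, 129 and 558, and the NF-kappaB inhibitor gene Nfkbia 1084, 1059 and 270.5. Interferon-stimulated genes were called 2 higher and 2 lower of 15 against B, and lymphoid transcription factors 3 higher and 5 lower of 20, with Bcl6, a germinal centre factor, at 221, 82.7 and 478. Ribosomal protein genes were called 5 higher and 7 lower of 38 against B and 7 higher and 3 lower of 38 against NK, with Rpl35 at 4436, 904 and 12223 and Rplp1 at 2804, 1547 and 751. Glycolysis genes were called 0 higher and 1 lower of 15 against B, and housekeeping genes 2 higher and 2 lower of 21, Gapdh reading 2418, 2615 and 2444. Against NK, housekeeping genes were called 6 higher and 3 lower of 22 on the array.

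Cytokine genes were called 0 higher and 2 lower of 6 against B and 1 higher and 2 lower of 7 against NK, and cytokine and chemokine receptors 1 higher and 3 lower of 15 and 3 higher and 6 lower of 20, with Ifngr1 at 227, 1123 and 607. The toll-like receptor list had 1 higher and 3 lower of 9 against B. Few genes of other blood and tissue cells were detected. The neutrophil list had 20 genes on the array, 3 detected in B, 3 in NK and 2 in NKB, and the dendritic cell list had 16 genes on the array, 4 detected in B, 2 in NK and 5 in NKB. The platelet list had 11 genes on the array, 0 detected in B, 0 in NK and 1 in NKB, the basophil and mast cell list 12 genes on the array, 1 detected in B, 2 in NK and 1 in NKB, the innate lymphoid list 17 genes on the array, 0 detected in B, 4 in NK and 2 in NKB, and the stromal and endothelial list 15 genes on the array, 1 detected in B, 2 in NK and 2 in NKB. Stem and progenitor genes were called 0 higher and 1 lower of 4 against B, the lower one being Lmo2 at 1848, 83.3 and 903. Of 11 immunoglobulin transcripts without a symbol, 8 were detected in B, 6 in NK and 7 in NKB. None of 4 male-specific Y-linked genes was detected on any array, and Xist, which silences an X chromosome in female cells, was detected on all 3 at 774, 296 and 2428.

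The first pattern weighed is the 925 genes above both B and NK in NKB. Noise of single probe sets as the whole cause is argued against by genes with 2 or more probe sets, where 58.0% of second probe sets lay above both if the first was called and 38.9% over all such genes, a difference of 0.191 (95% bootstrap interval over genes 0.150 to 0.233) against a planned limit of 0.1. All such genes were not matched to the called ones on brightness, so the size of the difference is uncertain. An excess of this kind is not particular to NKB. The same shares were 52.6% and 31.1% for genes above both others in B, and 57.0% and 29.9% in NK. Noise of the NKB array cannot be told apart from expression, because the planned test took only genes detected on an array, which brightness on NKB itself helps a gene to be, over all genes without a level the share above both was 8.81% against 7.03% of olfactory and vomeronasal genes (1.252 times, 1.005 to 1.635), many of those genes being dim on every array, and no replicate exists. RNA of kidney on the NKB array is a candidate source of part of the pattern, as a hypothesis found and tested on the same data: 15 (9 to 22) of 55 proximal tubule genes not seen before were at least 2-fold above both, at percentile 100 of random lists matched on the brighter of B and NK, against 0 of 25 for liver (39.2), 0 of 16 for muscle (26.3) and 0 of 15 for brain (37.9). A sort of spleen cells should remove kidney cells, but its gate is not given. The 3 kidney lists hold 8, 55 and 26 genes on the array, of which 8 (by construction), 15 and 3 were above both. Lists this short cannot cover most of the 925 genes, so the 26 found there do not measure how much of the pattern is kidney RNA. A biological difference between the populations stays open and untested.

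The second pattern is the presence of B-specific and NK-specific genes on the NKB array, for which a mixture of the sorted B and NK populations would give the same NK share from both gene sets. The share was 0.669 from genes higher in B and 0.155 from genes higher in NK, a gap of 0.515 (0.264 to 0.795). The genes higher in NK were not all NK-specific and included macrophage and erythroid genes. The planned limit of 0.2 did not allow for genes chosen on the same noisy values that set the shares. That choice gave a gap of 0.235 (0.0702 to 0.383) in simulated mixtures with an NK share of 0.3. At simulated shares of 0.1 and 0.5 the upper limits were 0.425 and 0.409. The observed gap lay above all 3 upper limits, though its own interval reached below them. The simulation added noise to observed values that already carry it. The other planned limit, genes above both more than 2 times as frequent as among olfactory and vomeronasal genes, was not reached over all genes (1.252 times, 1.005 to 1.635). With genes chosen on the first probe set and measured on the second the shares were 0.424 and 0.0491 and the gap 0.374 (-0.0734 to 0.472). With the fixed identity lists they were 0.538 and 0.290 and the gap 0.247 (-0.231 to 0.589). These intervals span both signs, so a mixture cannot be told apart from cells that express both sets, which may also be the cause. A mixture alone leaves Pax5 at 10954 in NKB against 1310 in B unaccounted for, but Pax5 is a leading gene with a single probe set. Of the 25 B cell identity genes, 2 were higher in NKB than in B and 9 lower. Dilution of lymphocyte transcripts by RNA from a non-leukocyte source was tested on 35 genes that leukocytes share, of which 3 lay above both and 3 below both. Their median for NKB minus the mean of B and NK was 0.029 (-0.560 to 0.284) on the log2 scale, where dilution was to give -0.5 or lower, and since the interval reaches that value dilution cannot be told apart from none.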
